A study of Glycine max with 6 samples.

How the data were processed

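Leaf RNA of field-grown soybean (Glycine max) was sequenced from 2 genotypes, HN44 and SN14, with 3 libraries each, numbered 1 to 3 in the labels. Per the labels' protocols, RNA was extracted with Trizol and libraries were made for a BGI platform. The series describes the genotypes as differing in water use efficiency. The labels give neither which of them uses water more efficiently nor whether the 3 libraries of a genotype came from separate plants, so p-values measure the spread between these libraries, which may be partly technical.

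The deposited values are FPKM per gene, given by the authors in 1 table with the gene's start, end and strand, per the file headers. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 1.4.5, without saying which step each was used for. The genome build is not given in the sources used here, and coordinates are printed as the authors' table gives them. The table holds 41759 genes, of which 38907 carry an NCBI gene number and 2852 carry an identifier that begins with BGI. Gene symbols, synonyms and chromosome numbers were taken from a RefSeq table of assembly Glycine_max_v4.0, which matched 37544 of the NCBI numbers; no coordinate was taken from it. A symbol or synonym other than a LOC number was found for 2267 genes, 1595 of them tested. FPKM is already scaled for depth and gene length, and read totals per library were not used here, so the depth and the counting error of each value are unknown. An FPKM of 0 is reported as listed at 0, and no fold is given against a genotype listed at 0 in its 3 libraries.

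The design written before the data were examined allowed for counts or FPKM; as the table holds FPKM, limma 3.58.1 with a variance trend was run in R 4.3.3 on log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 libraries were tested, with all 6 libraries, no covariate and Benjamini-Hochberg adjustment; the threshold was an adjusted p of 0.05. Fold changes are HN44 minus SN14 on that scale, with their standard errors (SE), and understate the change of low genes. On data simulated from the 27140 tested genes with 200 changed genes, the test for HN44 against SN14 recovered 19.1% of changes of 1 on the log2 scale, 59.1% of changes of 2 and 89.4% of changes of 4. Genes were drawn independently with the SN14 spread, and the changed ones came from the more abundant genes. Each HN44 library was drawn on its own.

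HN44-3 held values between those of HN44-1 and HN44-2 for nearly all genes that differed between them. This was found after the design was fixed. The planned fit with 6 libraries is therefore kept, HN44 levels are given as the mean ± SD of HN44-1 and HN44-2 (n = 2), SN14 levels as that of its 3 libraries (n = 3), and counts are repeated without HN44-3. In 20 simulated comparisons of HN44 against SN14 with 27140 genes and none changed, making the third HN44 library a mixture of the other HN44 libraries raised the median share of genes at an unadjusted p under 0.05 from 5.47% to 12.3%, and the highest number of genes past the adjusted threshold from 1 to 17. Genes were again drawn independently, while the real libraries share differences across many genes, so 17 is not an upper limit of false calls. The plan to leave out each library did not say whether the expression filter was to be applied again to the remaining 5 libraries. Both ways were run without HN44-3, giving 150 and 15 genes, and the fit on the genes kept with 6 libraries was chosen as the planned form after both counts had been seen. Both are printed. Applying the filter again to 2 HN44 libraries dropped 863 genes. The 83 of the 150 calls among them had a median SN14 mean of 0.02 FPKM. Some dropped genes had more in SN14, such as LOC547562 at a mean of 0.73 FPKM.

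The 47 gene lists fixed before the data were examined match on gene descriptions, which neither table used here holds, so they were not tested. In their place 45 lists were written as patterns on symbols and synonyms, after the columns, the most abundant genes and the correlations between libraries had been seen and before any test. Lists with at least 5 tested members, 39 in all, were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 39. They were tested again with an estimated correlation and with fry. Results by fry are those of its directional test. Its test for changes in either direction was not used for calls.

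Genes are named by fixed rules. Among genes past the threshold with at least a 2-fold change, no overlap between the groups and a mean of at least 5 FPKM in the higher group, the 8 with the largest fitted fold change in each direction were taken. The same rule was run over genes with a symbol or synonym, an addition written after the counts of calls and the position of HN44-3 were known and before gene-level results were viewed. In each called list, and in the aquaporin, ABA, stomata, LEA, clock, photosystem and NBS-LRR lists whether called or not, the 2 members with the smallest p in each direction were taken, or 1 member as a value where none passed. Among genes found in 1 genotype alone, at 1 FPKM or more in its 3 libraries and at 0 in the 3 of the other, the 3 with the highest mean in each were taken. Alternatives covered scaling, the variance trend, the filter, the pseudocount, a replicate block, leaving out each library and, added later, HN44-2 alone against SN14 and the re-applied filter.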

Results

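Expression was measured in leaves of 2 soybean genotypes, HN44 and SN14, as FPKM in 3 libraries each. Between 37244 and 37939 genes had a value above 0 in a library, and between 26057 and 26894 reached 1 FPKM. The 10 most abundant genes took 12.6% of the FPKM total in HN44-1, 17.3% in HN44-2 and 14.5% in HN44-3, against 19.3%, 19.9% and 20.6% in SN14-1, SN14-2 and SN14-3. The first principal component of the tested genes held 54.2% of the variance and separated the genotypes. HN44-1 lay at -84.9 on it and HN44-2 at -19.9, with HN44-3 between them at -56.6. The SN14 libraries lay at 75.05, 24.7 and 61.6. The libraries of each genotype were thus also spread along this component, which does not hold genotype alone. The median absolute log2 difference was 0.296 between HN44-2 and SN14-2 and 0.355 between HN44-1 and HN44-2. The Pearson correlations of these pairs were 0.918 and 0.921.

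HN44-3 took values between those of the other HN44 libraries. Of 1638 genes with a mean of at least 5 FPKM that differed over 2-fold between HN44-1 and HN44-2, HN44-3 lay between them in 1635, or 99.8%. The corresponding shares for the SN14 libraries, each set between the other two, were 40.5%, 69.0% and 64.2%. A weighted sum of 0.57 times HN44-1 and 0.43 times HN44-2 gave the HN44-3 values with a median absolute log2 deviation of 0.06 over 16039 genes. HN44-3 was therefore left out of the HN44 means. The p-values and SE of the fit with 6 libraries treat it as a separate replicate and may be too small. The SE of fold changes below are from that fit unless stated.

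**Figure D1:**
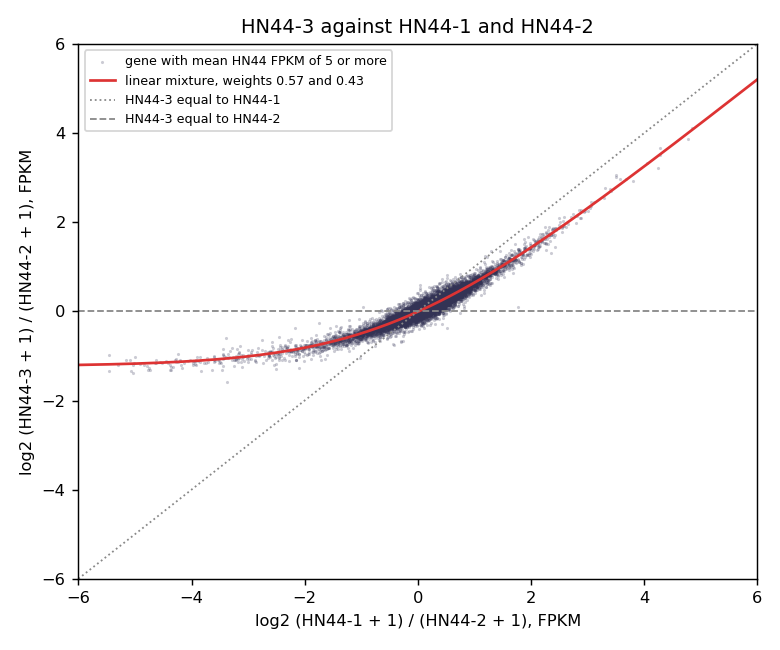
Each point is a gene with a mean HN44 level of at least 5 FPKM; the horizontal axis is the log2 ratio of HN44-1 to HN44-2 and the vertical axis that of HN44-3 to HN44-2, both of FPKM + 1. The points follow the curve of a linear mixture with weights 0.57 and 0.43, and lie away from the lines on which HN44-3 would equal HN44-1 or HN44-2.

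The comparison of HN44 with SN14 addresses which leaf transcripts differ between genotypes of different water use efficiency. Of the 8 named genes with the largest fold change in each direction, all but VSPA had a mean under 3 FPKM in 1 genotype. SLTI114 stood at 435 ± 109 FPKM in HN44 (SD, n = 2) and 0.033 ± 0.029 in SN14 (SD, n = 3). The leaf storage protein genes VSPA and VSPB, whose products accumulate in leaf vacuoles as a nitrogen reserve, were lower in HN44: VSPA at 28.6 ± 37.7 against 1160 ± 828 FPKM, and VSPB (LOC547820) at 0.37 ± 0.42 against 46.0 ± 32.0. The ammonium transporter gene AMT1.5 stood at 0.41 ± 0.36 FPKM in HN44 and 39.3 ± 19.6 in SN14. The ferritin gene SFERH-2, for an iron storage protein, was higher in HN44, at 655 ± 15 against 116 ± 16.4 FPKM.

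With all 6 libraries, 1025 of 27140 genes passed an adjusted p of 0.05 in limma, 633 higher and 392 lower in HN44, and 820 of them changed at least 2-fold. Without HN44-3 the count was 150 on the same genes, 105 higher and 45 lower, and 15 when the expression filter was applied again to the 5 libraries, 5 higher and 10 lower. The 150 and the 15 were each also past the threshold in the same direction with 6 libraries. Of the 150, 83 were not tested under the re-applied filter and 52 were tested and did not pass. The share of higher genes among the calls was 61.8% as deposited, 47.6% after median-of-ratios scaling and 49.6% after quantile normalization. The median log2 fold change of all tested genes was 0.17 as deposited and 0.02 after median-of-ratios scaling, so that directions of changes near 0.17 depend on the scaling. That scaling also ended the calls of VSPA, WRKY55, WRKY49, GASA28 and NAC22, with adjusted p from 0.054 to 0.109.

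**Figure D2:**
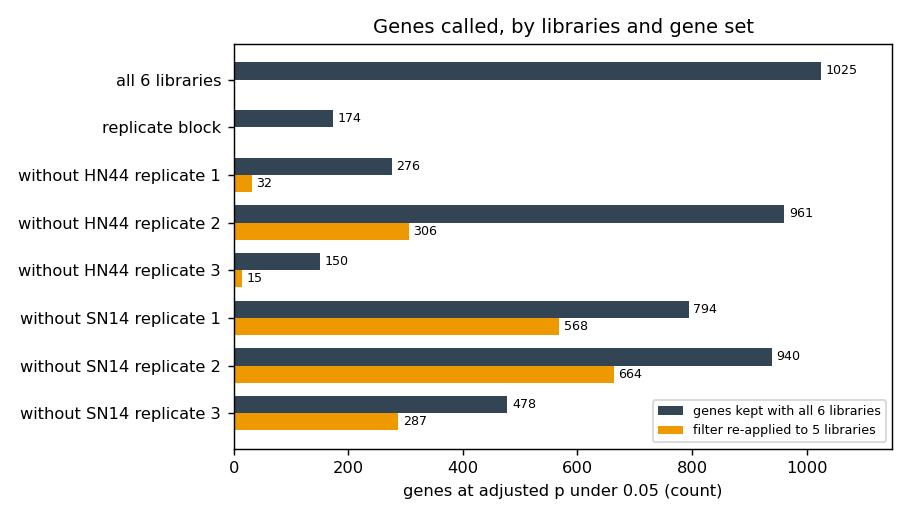
Bars give the number of genes at an adjusted p under 0.05 in limma with all 6 libraries, with a replicate block and without each library; dark bars keep the genes tested with 6 libraries and orange bars apply the expression filter again. The count is 1025 with 6 libraries and 150 or 15 without HN44-3.

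Among the 8 genes with the largest rise, 3 lie together on chromosome 2. Between LOC100805716 and SLTI114 lies LOC100806774 (2527246 to 2527808). It stood at 14.3, 7.41 and 9.78 FPKM in HN44-1, HN44-2 and HN44-3 and was listed at 0 in SN14. SLTI114 (2533522 to 2534705) had a log2 fold change of 8.71 ± 0.18 (SE; adjusted p = 1.4e-05, and 0.000619 without HN44-3). LOC100805716 (2511359 to 2520118) stood at 242 ± 35.7 FPKM in HN44 and 0.247 ± 0.254 in SN14. LOC100814809 (2534006 to 2616013), whose span overlaps SLTI114 so that reads of the pair may be divided between them, stood at 130.01 ± 1.5 and 2.13 ± 3.68 FPKM; its adjusted p was 0.00997 with 6 libraries and 0.0642 without HN44-3. LOC100783381 on chromosome 7 rose from 1.39 ± 0.45 to 53.8 ± 4.49 FPKM, with an adjusted p of 0.000178, and remained past the threshold without HN44-3 under both gene sets (adjusted p = 0.00405 and 0.0145). BGI_novel_G002261 on chromosome 16 stood at 25.6 ± 1.73 against 0.047 ± 0.081 FPKM. It has the same span as BGI_novel_G002260 and BGI_novel_G002263, so reads may be divided among them. BGI_novel_G000001, on a sequence for which no chromosome was matched, stood at 50.3 ± 16.3 against 1.76 ± 2.00 FPKM.

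The gene with the largest fall was BGI_novel_G001976 on chromosome 14 (7576270 to 7590214), at 0.62 ± 0.88 FPKM in HN44 and 818 ± 141 in SN14. Its log2 fold change was -9.01 ± 0.32 (SE), with an adjusted p of 0.000133 with 6 libraries and of 0.00253 and 0.00619 without HN44-3 under the 2 gene sets. BGI_novel_G001977 lies within its span, and its 388 ± 291 FPKM in SN14 may share reads with it; its adjusted p without HN44-3 was 0.0505. BGI_novel_G000440 on chromosome 3 stood at 0.42 ± 0.53 against 74.9 ± 50.7 FPKM. Its limma adjusted p without HN44-3 was 0.0217 and 0.0588 under the 2 gene sets. LOC100800387, a cupin gene with the synonym GmCUPIN17.1, stood at 1.23 ± 0.26 against 64.2 ± 36.6 FPKM. Without HN44-3 it had a limma adjusted p of 0.0425 and 0.0869 under the 2 gene sets. LOC732576 stood at 2.13 ± 2.79 against 66.1 ± 49.7 FPKM (limma adjusted p = 0.019, and 0.102 without HN44-3). AMT1.5 fell by 4.81 ± 0.35 on the log2 scale (adjusted p = 0.00116) and passed without HN44-3 under both gene sets (adjusted p = 0.0121 and 0.042). VSPB fell by 4.94 ± 0.44, with a limma adjusted p of 0.00301 that became 0.0236 and 0.0588 without HN44-3 under the 2 gene sets. VSPA fell by 5.79 ± 1.17, with a limma adjusted p of 0.0482 that became 0.176 without HN44-3.

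**Figure D3:**
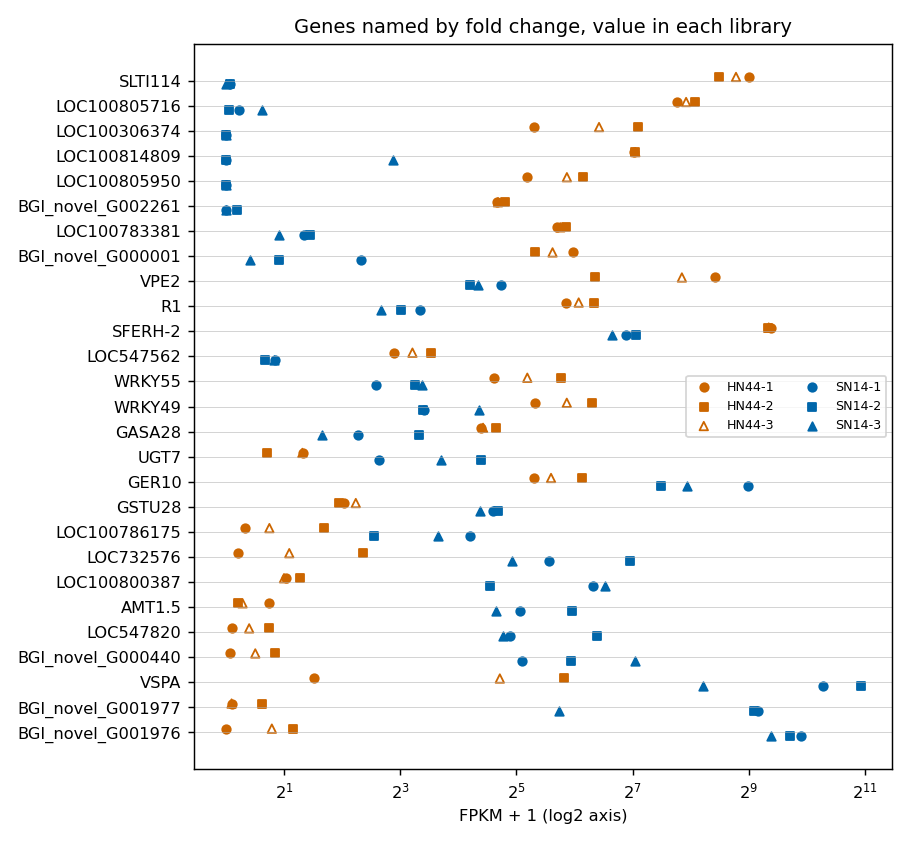
FPKM + 1 of the genes with the largest fold changes, on a log2 axis, in each HN44 library (orange, HN44-3 as open triangles) and each SN14 library (blue). The genes run from BGI_novel_G001976, at a mean of 818 FPKM in SN14, to SLTI114, at a mean of 435 FPKM in HN44-1 and HN44-2.

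Among genes with a symbol, those that rose most after SLTI114 were VPE2, R1 and SFERH-2. VPE2, for a vacuolar processing protease, stood at 212 ± 185 FPKM in HN44 and 20.8 ± 4.38 in SN14, and its adjusted p of 0.0269 became 0.143 without HN44-3. R1, from the protease inhibitor list, rose by 3.08 ± 0.23 on the log2 scale, from 7.2 ± 1.9 to 68.3 ± 16.2 FPKM (adjusted p = 0.00127, and 0.0154 without HN44-3). SFERH-2 rose by 2.49 ± 0.17 (SE, which was 0.24 without HN44-3), with a limma adjusted p of 0.000873, and of 0.0144 without HN44-3. With the filter applied again, these last 2 stood at 0.052 and 0.0518. Among those that fell, the glutathione S-transferase gene GSTU28 went from 22.6 ± 2.59 in SN14 to 2.96 ± 0.16 FPKM in HN44 and passed under each of these fits (adjusted p = 0.000914, 0.0117 and 0.042). The YABBY transcription factor gene LOC100786175 (GmYABBY7), the germin gene GER10 and the glycosyltransferase gene UGT7 had log2 fold changes of -2.54, -2.46 and -2.45, and their adjusted p without HN44-3 ranged from 0.151 to 0.216.

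Transcription factor, heat shock and defence genes were compared as groups. Their member counts stand beside 1025 of 27140 for all tested genes. WRKY genes, which act in defence and stress responses, had 4 of 46 measured members that rose, none that fell and 42 that did not pass; 5 rose adjusted over the list alone. WRKY55 stood at 38.7 ± 21.3 FPKM in HN44 against 7.60 ± 2.31 in SN14, and WRKY49 at 58.4 ± 27.8 against 12.9 ± 5.76. In the heat shock list 2 of 32 rose, HSF-31 (12.8 ± 5.14 against 4.41 ± 0.25 FPKM) and HSP90A1 (9.43 ± 4.01 against 2.42 ± 1.23), and in the NAC list 1 of 26, NAC22 (14.2 ± 3.60 against 6.94 ± 0.76); both lists had 2 members past the threshold adjusted over the list alone. Without HN44-3 no member of these 3 lists passed over all genes, and 3 WRKY genes and no others passed adjusted over the list alone. As lists, these 3 had an adjusted p of 0.718 with an estimated correlation. Of 8 NBS-LRR genes, a class of disease resistance genes, 2 rose and 1 fell: LOC547562 and LOC100795233, which share the synonym KNBS1, lie near each other on chromosome 16 and may share reads, stood at 8.49 ± 2.93 against 0.73 ± 0.11 and at 4.66 ± 1.10 against 0.34 ± 0.07 FPKM, and KR3 stood at 2.03 ± 0.30 against 9.88 ± 4.68. The KNBS1 pair also passed without HN44-3 on the same genes, and KR3 did not (adjusted p = 0.179).

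The lists of GASA peptides, aquaporins, photosystem, chlorophyll and haem, desaturase, phosphate and vegetative storage genes had negative medians in HN44 against SN14, and few members that passed. Each of these lists had an adjusted p of 0.718 with an estimated correlation, and none passed by fry. The GASA peptides, small proteins regulated by gibberellin, had a median log2 fold change of -1.69 over 17 members. The 1 member that passed over all genes, GASA28, went the other way, at 21.98 ± 2.94 against 5.01 ± 3.59 FPKM (adjusted p = 0.0451, and 0.197 without HN44-3). Adjusted over the list alone, 1 member rose and 1 fell, and 0 passed without HN44-3. The aquaporins had a median of -0.34 over 42 members, none of which passed in limma (16 at an unadjusted p under 0.05); the smallest p belonged to LOC100817754 (TIP2-2), at 35 ± 24.3 against 95.4 ± 12.1 FPKM (adjusted p = 0.0642). No member passed in the photosystem list (7 members, median -0.37), the chlorophyll and haem list (5 members, median -0.67) or the fatty acid desaturase list (21 members, median -0.44; 4 fell and 1 rose adjusted over the list alone, and 0 without HN44-3). At an unadjusted p under 0.05 in limma these lists had 3, 2 and 8 members, where 7419 of all 27140 tested genes were under it. Their members with the smallest p were the light-harvesting protein gene LOC547819 at 83.8 ± 101 against 687 ± 544 FPKM, CHLI at 127 ± 68.5 against 275 ± 82.1, and SLD1.4 at 11.8 ± 11 against 68.8 ± 30.4. In the phosphate list 1 of 23 fell, PAP14 (0.12 ± 0.01 against 1.48 ± 0.21 FPKM; adjusted p = 0.0126, and 0.108 without HN44-3), and in the vegetative storage list 2 of 5 fell, VSPA and VSPB.

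By camera with the preset correlation, 10 of 39 lists passed: WRKY (adjusted p = 0.00289), heat shock (adjusted p = 0.0139) and NAC (adjusted p = 0.0229) higher in HN44, and GASA (0.00136), aquaporins (0.00289), desaturases (0.00356), photosystems (0.00803), vegetative storage (0.0294), phosphate (0.034) and chlorophyll and haem (0.0496) lower. With an estimated correlation none passed by camera (adjusted p = 0.718 for each of the 10), and none passed by the directional test of fry. Without SN14-1 on the same genes, the WRKY, heat shock and NAC lists did not pass by camera with the preset correlation. The 5 lists that passed were lower in HN44. With the filter applied again 9 lists passed, 1 higher in HN44 (WRKY) and 8 lower. At an unadjusted p under 0.05 the estimated correlation and fry gave 0 and 11 lists. Splits of the 6 libraries that mixed the genotypes called between 6 and 11 lists by camera with the preset correlation. After median-of-ratios scaling 7 lists passed, and the vegetative storage, phosphate and chlorophyll lists did not; the medians of the 10 lists kept their sign. In 7 of the 10 lists the median differed between 2 libraries of 1 genotype by at least as much as between the genotypes; the exceptions were WRKY, heat shock and chlorophyll and haem. The GASA median differed by -1.66 between HN44-1 and HN44-2 and by -2.17 between SN14-2 and SN14-1, the photosystem median by -0.76 between HN44-1 and HN44-2, and the aquaporin and desaturase medians by 0.996 and 0.697 between SN14-1 and SN14-3.

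**Figure D4:**
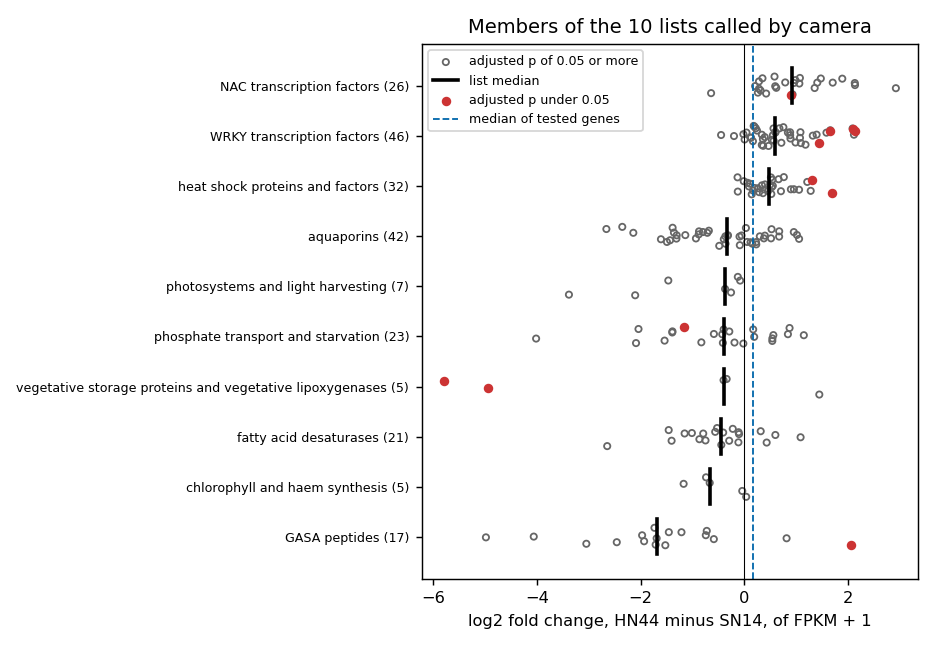
Log2 fold change, HN44 minus SN14, of each tested member of the 10 lists called by camera with a preset correlation, with the number of members in brackets. Black bars are list medians, from 0.92 for NAC to -1.69 for GASA, red points are members at an adjusted p under 0.05, and the dashed line is the median of all tested genes, 0.17.

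In the stomatal, clock, abscisic acid and LEA lists, taken as tied to water use, no gene passed the threshold. Over all 27140 tested genes, 1025 passed in limma and 7419 had an unadjusted p under 0.05. At that share, lists of this size would hold few or none past the threshold. None of 14 stomatal genes and none of 15 clock genes passed in limma over all genes (2 and 6 at an unadjusted p under 0.05); adjusted over the list alone, 0 stomatal genes and 2 clock genes, both higher in HN44, passed, and none of either without HN44-3. The smallest p among stomatal genes was that of ICE2, at 4.43 ± 2.33 FPKM in HN44 and 12.4 ± 4.12 in SN14 (adjusted p = 0.0784), and among clock genes that of MYB114, with the synonym GmLHY2b, at 248 ± 37.3 against 134 ± 23.5 (adjusted p = 0.0547). The lists for abscisic acid and LEA proteins had fewer than 5 tested members and were not tested as lists. ZEP, whose enzyme acts upstream of abscisic acid, stood at 347 ± 156 against 165 ± 58.9 FPKM (adjusted p = 0.118), and LEA-2 at 60.6 ± 26.9 against 34.7 ± 10.3 (adjusted p = 0.158).

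Some genes had values in 1 genotype alone. In HN44, 54 genes reached 1 FPKM in its 3 libraries and were listed at 0 in those of SN14, and in SN14 28 genes did the reverse. Of these, 32 and 22 carry BGI identifiers. The counts are of gene models, some of which share a place and may share reads. In HN44, BGI_novel_G000377, BGI_novel_G000378 and BGI_novel_G000380 on chromosome 3 overlap, and in SN14 BGI_novel_G000526 and BGI_novel_G000527 have the same span. The most abundant in HN44 was LOC100306374 on chromosome 10, at 38.3, 136 and 84.8 FPKM in HN44-1, HN44-2 and HN44-3, followed by LOC100805950 on chromosome 11, at 35.2, 69.6 and 57.5, and BGI_novel_G002186 on chromosome 15, at 6.88, 23.2 and 14.7. In SN14 the most abundant were BGI_novel_G002407 on chromosome 17, at 12.3, 12.03 and 18.5 FPKM, BGI_novel_G001224 on chromosome 9, at 7.58, 8.45 and 17.5, and LOC102665424 on chromosome 15, at 1.16, 8.74 and 18.4. LOC100805950 and BGI_novel_G001224 overlap another gene with a mean of at least 1 FPKM in the genotype where they are listed at 0, so reads may be divided differently there. BGI_novel_G002186 overlaps BGI_novel_G002184, also found in HN44 alone, and BGI_novel_G001224 overlaps BGI_novel_G001221, also found in SN14 alone. Of the 54 and 28 genes, 53 and 23 passed the adjusted p with 6 libraries and 35 and 6 without HN44-3. The rule that chose these genes, in which HN44-3 took part, already sets the groups apart in these libraries. Passing therefore adds no separate support. With the filter applied again, the HN44 genes could not be tested, since only 2 libraries with a value are left, and 2 of the SN14 genes passed.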

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

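The fits with a re-applied filter, HN44-2 alone and the lists on symbols were chosen after seeing the data. Leaving out each library on the genes kept with 6 libraries gave 150 to 961 genes past the threshold, against 1025, and 150 to 938 with at least a 2-fold change, against 820. The lowest was without HN44-3, and the count was 276 without HN44-1 and 478 without SN14-3. The highest, 961, was without HN44-2, which left HN44-1 and HN44-3, with a Pearson correlation of 0.976. All of these fits but the one without HN44-3 treat HN44-3 as a separate replicate, so their counts may be too high. With the filter applied again to the 5 libraries the counts were 32, 306 and 15 without HN44-1, HN44-2 and HN44-3, for both thresholds, and 568, 664 and 287 without SN14-1, SN14-2 and SN14-3 (551, 664 and 286 with at least a 2-fold change). These refits test fewer libraries and, with the filter, fewer genes, such as 26277 without HN44-3. The re-applied filter drops genes that reach 1 FPKM only in the genotype that lost a library. It therefore changes counts and directions by construction. HN44-2 alone against SN14 gave 5 genes, assuming that the lone library varies like SN14. The replicate block gave 174 for both thresholds; nothing in the labels pairs the numbers, and the deviations of same-numbered libraries from their group means correlated at -0.223, -0.436 and 0.0296 across genes. No library correlated best with its own number. A filter of 5 FPKM left 531 genes with at least a 2-fold change, out of 15895 tested in place of 27140, so its lower count comes with fewer genes tested. A pseudocount of 5 left 360, where the larger pseudocount shrinks fold changes by construction. Scaling, the trend and the other pseudocount kept both counts within 1.5 times.

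The number of lists, 10, fell to 0 with an estimated correlation and to 0 by fry, and ranged from 5 (without SN14-1, none of them higher in HN44) to 15 (without SN14-3) when a library was left out. The replicate block gave 12. Of 45 named genes tested, none changed direction under an alternative; median-of-ratios scaling put VSPA, WRKY55, WRKY49, GASA28 and NAC22 above the threshold (adjusted p = 0.054, 0.0554, 0.0616, 0.0616 and 0.109), the block did so for 12 genes, HN44-2 alone for 31, and leaving out a library for between 5 (without HN44-2 or SN14-2) and 16 (without HN44-3). With the filter applied again 37 named genes were tested in each fit, and between 7 (without SN14-2) and 23 (without HN44-3) lost their call, with 21 without HN44-1. Genes listed in 1 genotype alone numbered 82, against 21 at a floor of 5 FPKM (19 in HN44 and 2 in SN14) and 124 when up to 0.1 FPKM was allowed in the other genotype (45 in SN14). For SN14 the number ranged from 33 to 58 with a library left out, the highest without SN14-1. The alternatives for counts (edgeR, DESeq2 and voom) and for transcript rows were not run, as the values are FPKM per gene. Depth is unknown, so what it limits could not be stated.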

Other observations

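Of 15 measured genes of the iron and metal list, 3 rose in HN44, each for a ferritin, an iron storage protein; ferritins were not tested as a group. They were SFERH-2, H-1 (370 ± 232 FPKM in HN44, SD, n = 2, against 81.6 ± 5.29 in SN14, SD, n = 3; limma adjusted p = 0.0288, and 0.155 without HN44-3) and SFERH-4 (25.2 ± 4.95 against 9.18 ± 0.98; adjusted p = 0.0119, and 0.106 without HN44-3). SFERH-3 stood at 269 ± 27.9 against 149 ± 38.5 FPKM. Without HN44-3, 1 of the 15 passed, SFERH-2, and the list as a whole had an adjusted p of 0.391 by camera. In the nitrogen list AMT1.3 stood at 128 ± 27.1 against 55.5 ± 17.7 FPKM (adjusted p = 0.0474, and 0.236 without HN44-3), while AMT1.5 was lower in HN44 in both fits. These genes, and those of the next paragraph, were chosen after their values were seen.

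Of 74 bZIP genes 3 rose, BZIP68, BZIP53B and LOC780550 (bZIP53A), the last at 115 ± 14.9 against 53.5 ± 8.28 FPKM; none of the 3 passed without HN44-3 (adjusted p from 0.149 to 0.219). The gibberellin synthesis gene GA20OX7 stood at 0.095 ± 0.134 FPKM in HN44 and 3.66 ± 1.07 in SN14 (adjusted p = 0.00462, and 0.0425 without HN44-3). The sugar transporter gene SWEET29 stood at 55.1 ± 14.6 against 20.8 ± 2.47 FPKM (adjusted p = 0.0187, and 0.139 without HN44-3).

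The tests below on HN44-3, on genes listed at 0 and on the splits for genes were chosen after their results were seen; those on the clock, on gene span and on the splits for lists were written before.

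HN44-3 lay between HN44-1 and HN44-2 in 99.82% of the genes that differed between them. The weight of HN44-1 was 0.567 where it was the higher and 0.583 where HN44-2 was, so 1 linear weight served both directions, while on a log scale the weights were 0.683 and 0.428. A pool of the same reads is argued against by genes at 0 in both HN44-1 and HN44-2, of which 31.3% were above 0 in HN44-3. A separate sample with its own spread is argued against by abundant genes, at a mean of at least 100 FPKM, where the median absolute log2 deviation from the mixture was 0.0273, against 0.254 as the smallest value for an SN14 library. A library made from mixed leaf material or RNA of the other HN44 samples remains a candidate explanation; no biological explanation was tested.

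The differences between HN44-1 and HN44-2 followed those between SN14-2 and the other SN14 libraries, with r = 0.374 against SN14-1 and 0.363 against SN14-3 across 27140 genes, which are not independent, while r with SN14-1 minus SN14-3 was -0.0534. If harvest at different hours were the cause, the 15 clock genes should differ more than other genes. Their median absolute log2 difference between HN44-1 and HN44-2 was at percentile 15.66 of 10000 random lists matched on expression, which argues against it there; for SN14-2 against SN14-1 and SN14-3 it was at 91.01 and 74.11. For RNA breakdown that depends on length, only gene span from start to end was at hand. Its correlation with the differences had a smallest size over the 3 pairs of 0.0222, with opposite signs in HN44 (0.107) and SN14. Span is not transcript length, so breakdown that depends on transcript length cannot be judged from it. An axis such as leaf age, which the labels do not record, stays open.

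Of the 82 genes listed at 0 in 1 genotype, 29.27% overlapped another gene with a mean of at least 1 FPKM in that genotype. Among tested genes the share was 5.61%, counted on SN14 means alone and not matched on the kind of identifier. BGI identifiers were carried by 1820 of 27140 tested genes, but by 32 of the 54 HN44 genes and 22 of the 28 SN14 genes. The 2 shares are therefore not a like comparison. A different division of reads among overlapping gene models may account for part of the 82 and cannot be told apart from a difference in expression there. On chromosome 12, LOC102660202 (38340955 to 38343753) was found in HN44 alone and LOC106795349 (38335262 to 38343753), which spans it, in SN14 alone. As a hypothesis, segments missing or divergent in 1 genotype could account for others: 9 of the 82 had a neighbour of the same genotype within 100 kb that they did not overlap, against a median of 2 and a highest of 11 in 1000 random draws of tested genes, and a highest of 10 in draws matched on the kind of identifier. A gene broken into several models would also give such neighbours. The neighbours lay on chromosomes 3, 6 and 18. On chromosome 2, LOC100806774 was not among them. Nearby SLTI114, LOC100805716 and LOC100814809 had a value above 0 in at least 1 SN14 library and so fell outside the rule. On chromosome 6, BGI_novel_G000858 overlapped BGI_novel_G000861, and BGI_novel_G000862 overlapped BGI_novel_G000864, so a place was counted more than once. The draws took single genes without such repeats, so the comparison cannot decide for missing segments. The genome sequence of neither genotype was used here.

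The 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 1025 genes, 820 with at least a 2-fold change, and was the 1 split with as many. The highest of the others was 0 by limma, with up to 3035 genes at an unadjusted p under 0.05. The other splits mix the genotypes, which puts any difference between them into the spread within groups and lowers their calls. The real split also keeps HN44-3 beside the libraries it lies between. The contrast in gene counts therefore adds no separate support. For lists by camera, 3 of the 10 splits gave at least the real 10, and the highest other gave 11. The groups did not overlap in 33.9% of tested genes, where chance gives 10% for 3 against 3 separate libraries; without HN44-3 the share was 35.4%, where chance gives 20% for 2 against 3.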
